A study of Drosophila melanogaster with 33 samples.

How the data were processed

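Eye-antennal imaginal discs of Drosophila melanogaster were taken 5 days after egg laying from larvae kept at 25°C, with at least 30 discs per sample, and 3' end libraries (QuantSeq 3' mRNA-Seq, forward) were made and sequenced, per the labels' protocols. The values analysed are counts per gene and library, as deposited by the authors. Per the submitters' processing notes, reads were trimmed with cutadapt, examined with FastQC and aligned to the dm6 genome with STAR 2.6.1d, and the counting tool, its strand setting and the annotation are not given in the sources used here. Values of overlapping, antisense or paralogous genes are uncertain for that reason. The counts came in 3 tables with the same 16727 gene symbols in the same order. Of these symbols 12512 were current in the annotation, 4062 were older names with a single match, 42 were older names with several matches and 111 had no match. Positions were found for 16574. Genes are named by the symbols of the tables, with the current name, where it differs, given here (dm is Myc, os is upd1, th is Diap1, IM1 is BomS1, E2f is E2f1, dys is dysf, Hr46 is Hr3, phm is phtm, CG9510 is Argl, CG31477 is ATPsynepsilonL) or in brackets at first use, and without the prefix that current names of noncoding RNAs carry.

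The 33 libraries formed 8 groups by their labels. Both eyFLP groups, both optix groups and the run 1 libraries of MARCM ctrl and MARCM yki3SA were fitted together (20 libraries, 1 mean per group). The 23 MARCM libraries were fitted together with the sequencing run as a term. The single run 2 yki3SA library was assumed to vary like the other groups. Genes were kept with filterByExpr, libraries scaled with TMM factors, and each comparison tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, robust, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic and are approximate. The 7 comparisons were eyFLP wts- against eyFLP ctrl, optix yki3SA against optix ctrl, MARCM yki3SA against ctrl, MARCM sd- against ctrl, MARCM yki3SA sd- against sd-, MARCM yki3SA sd- against yki3SA, and the interaction of yki3SA and sd-. Group means of the MARCM model are those of run 1 unless run 2 is named. A fold against a group in which every library had 0 counts was computed against a floor of 3 counts over the group's libraries together and is a lower bound, and medians were also computed with such genes at their bounds.

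The comparisons, the 28 gene lists and the rule for naming genes were fixed before the data were examined. The genes yki, wts and sd came first. For each comparison, up to 10 genes with the largest rise and up to 10 with the largest fall were named among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups (within run 1 for the MARCM model, and not asked for the interaction). For each list up to 4 called members with the largest change were named, or the members with the highest mean where none passed. For the 3 models together, up to 10 genes per direction were named in the order of their smallest change. The lists were Yki target genes, Hippo pathway components, cell cycle and DNA replication, ribosome biogenesis and Myc growth programme, cytosolic ribosomal proteins, apoptosis, JNK with JAK-STAT and wound response, photoreceptor differentiation and ommatidial assembly, neuronal genes, retinal determination and eye progenitors, antennal selectors and antennal disc, peripodial epithelium, wing and other disc selectors, Notch targets, EGFR with Dpp and Wg pathway read-outs, ecdysone response and developmental timing, cuticle proteins, cell adhesion with cytoskeleton and extracellular matrix, innate immunity and stress peptides, heat shock and oxidative stress, glia, hemocytes, muscle and myoblasts, fat body and serum proteins, trachea, salivary gland, central brain neuroblasts and neurons, and sex-specific transcripts. Some genes are members of several lists. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 28 lists of a comparison, again with an estimated correlation, and with fry, which asks whether a list moves on balance one way without comparing it with other genes.

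Genes called in the same direction in the eyFLP, optix and MARCM models were counted beside the number that independent lists would share. Genes raised, or lowered, in both the eyFLP and optix models were followed in the MARCM contrasts beside 10000 random gene sets matched on mean expression in 20 bins. The share of called genes was compared between chromosome arms with Fisher's exact test, and no arm passed after adjustment in any comparison.

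Alternatives were DESeq2-type and upper-quartile scaling, no filter and a mean of at least 10 CPM, DESeq2 1.42.0 and limma-voom, a log2 fold change of at least 1, fits of only the groups compared, run 1 alone, no run term, the replicate number as a block, and each library left out in turn. Run 2 alone, sample quality weights, the mean log2 level of spok and phm as a covariate, sets and shared genes from fits of only the groups compared, and fits without 3 doubted libraries were chosen after seeing the data. Replicate numbers were checked for pairing: deviations from the group means of the 5 same-numbered pairs of MARCM ctrl and yki3SA in run 1 had a Pearson's r across genes, which are not independent replicates, of 0.173 to 0.494, and 2 of 120 matchings of the numbers, the real one included, gave a mean r as high. Only 3 of the 5 ctrl libraries had their highest r with the yki3SA library of their own number. Replicate 4 of ctrl had 0.275 with its own number and 0.484 with yki3SA replicate 5. The numbers therefore go with a structure that these libraries share, but pairing is not established, and the labels do not state it. Values with the replicate block are given where they change a call of that comparison. The fits were tested on simulated data with 200 changed genes per comparison. Of 2-fold and 4-fold changes, 64% and 95% were recovered for eyFLP wts- against ctrl, 62% and 96% for MARCM yki3SA against ctrl, 71% and 88% for yki3SA sd- against sd-, and 34% and 83% for the interaction, with 4 to 9 false calls in each. The simulated groups had the same spread and no structure between libraries. In the real run 1 data Spearman's rho between libraries was 0.866 to 0.950 in yki3SA sd- and 0.977 to 0.995 in ctrl. These rates therefore need not hold for comparisons with yki3SA sd-. For every MARCM comparison 60 splits of the libraries within runs were fitted, the real one included. Tables and figures were made with R and Python 3.11.15 (matplotlib 3.10.9).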

Results

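Messenger RNA was measured in eye-antennal imaginal discs, the larval epithelia that form the eye, antenna and head capsule of adult Drosophila melanogaster. Discs were collected 5 days after egg laying, with at least 30 discs in each sample, and 33 libraries in 8 groups were sequenced from the 3' end of polyadenylated transcripts. Yorkie (Yki) is the transcriptional co-activator at the end of the Hippo pathway. The kinase Warts (Wts) keeps it out of the nucleus, and Scalloped (Sd) is the DNA-binding protein through which it reaches most of its known targets. In the eyFLP model, discs that were largely mutant for wts (2 libraries) were set against discs with control clones (3 libraries). In the optix model, a form of Yki with altered inhibitory phosphorylation sites (yki3SA) was expressed under the optix driver (2 libraries), with a luciferase hairpin as its control (3 libraries). In the MARCM model, which positively marks mitotic clones, 7 control, 6 yki3SA, 5 sd mutant (sd-) and 5 yki3SA sd- libraries were compared. Whole discs were used, so every library of these clonal experiments also holds RNA from cells outside the clones. The MARCM libraries came from 2 sequencing runs. Run 1 held 5 control, 5 yki3SA, 3 sd- and 3 yki3SA sd- libraries, and run 2 held 2, 1, 2 and 2. In run 2 the control and yki3SA clones were made on another chromosome arm and with another Gal4 driver than the sd- clones.

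Total counts per library were 8407412 to 9874923 in eyFLP ctrl, 10194911 to 10790842 in eyFLP wts-, 6927152 to 11181616 in optix ctrl and 8473218 to 11454139 in optix yki3SA. In run 1 of the MARCM model they were 8084987 to 15273835 in ctrl, 7383459 to 11952153 in sd-, 5838706 to 14695172 in yki3SA and 4874192 to 9946422 in yki3SA sd-. Run 2 was deeper, at 18627105 to 19128356 in ctrl, 18701236 to 18921185 in sd-, 18528214 in the single yki3SA library and 17071389 to 18516696 in yki3SA sd-. Between 6787 and 8995 genes per library had at least 10 counts. Levels are normalized CPM (counts scaled to library size) as mean ± SD, log2 fold changes are given ± standard error, and adjusted p-values come from edgeR's quasi-likelihood test. Lower bounds set against a group without counts cover counting error only. Nothing in the sources used here states that replicates are separate crosses or collections, so the p-values measure the spread between these samples.

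The manipulated genes were examined first. Counts of yki were 63.1 ± 9.80 CPM in eyFLP ctrl (n = 3) and 57.5 ± 14.7 CPM in eyFLP wts- (n = 2), and 7.81 ± 8.81 CPM in optix ctrl (n = 3) against 27.6 ± 25.1 CPM in optix yki3SA (n = 2). In run 1 of the MARCM model yki stood at 38.7 ± 18.4 CPM in ctrl (n = 5), 46.4 ± 39.0 CPM in sd- (n = 3), 58.3 ± 15.6 CPM in yki3SA (n = 5) and 6.22 ± 3.82 CPM in yki3SA sd- (n = 3). In run 2 yki stood at 65.6 ± 2.17 CPM in ctrl (n = 2), 64.1 ± 0.89 CPM in sd- (n = 2), 105 ± 7.85 CPM in yki3SA sd- (n = 2) and 2146 CPM in the single yki3SA library. The fitted yki change was 1.72 ± 0.71 in MARCM yki3SA (adjusted p = 0.0663) and 1.78 ± 0.78 in optix yki3SA (adjusted p = 0.126), neither past the threshold. Whether the transgene carries the yki 3' end is not given in the sources used here, so these tags do not check the transgene in run 1. Transcripts of wts rose in eyFLP wts- discs, from 149 ± 5.67 CPM to 219 ± 18.8 CPM, by 0.55 ± 0.14 (adjusted p = 0.0062). Counts of sd remained in sd- discs, at 344 ± 61.0 CPM against 440 ± 35.0 CPM in ctrl in run 1, and at 221 ± 14.5 CPM against 233 ± 5.02 CPM in run 2. A 3' tag outside the altered part of an allele, in discs that keep other cells, checks neither the wts nor the sd genotype. In MARCM yki3SA discs both wts (1.12 ± 0.14) and sd (0.77 ± 0.10) rose, with the same sign in both runs.

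Loss of wts in eyFLP discs removes the brake on endogenous Yki and asks which transcripts follow. The JAK-STAT ligand upd3 rose from 0.066 ± 0.11 CPM (n = 3) to 10.4 ± 0.55 CPM (n = 2), by 6.98 ± 0.59. Ilp8, a relaxin-like peptide that delays metamorphosis when discs are damaged, rose from 1.10 ± 0.22 to 119 ± 4.00 CPM, by 6.74 ± 0.42. Both tyrosine decarboxylase genes rose, Tdc1 by 7.41 ± 0.59 and Tdc2 by 6.14 ± 0.62, and the cytochrome P450 gene Cyp6a17 rose by 8.33 ± 0.61. CG13215 and CG12607 had no counts in the controls and rose at least 866-fold and at least 156-fold. CG15279 (5.21 ± 0.45), CG9192 (5.04 ± 0.38) and the peptidoglycan receptor gene PGRP-SA (4.94 ± 0.49) completed the 10 largest rises. In the other direction the odorant receptor gene Or49b fell at least 93.1-fold, to no counts in 2 libraries. The serpin gene Spn43Aa (-7.31 ± 0.64), the villin-like gene qua (-7.08 ± 0.44), the homeobox gene Hmx (-6.89 ± 0.43) and CG14516 (superdeath, -6.39 ± 0.36) fell. So did CG34391 (DIP-delta, -6.32 ± 0.34), the pair-rule gene run (-6.23 ± 0.53), CG5873 (cysu, -6.21 ± 0.55), CG3812 (Agpat1, -6.20 ± 0.41) and the activin-type ligand gene Actbeta (-6.11 ± 0.57). All 20 genes had an adjusted p of 2.03e-07 or lower. Of 8693 genes tested, 2090 passed, of which 919 rose and 1171 fell, and 1269 of them changed at least 2-fold. Leaving out one library at a time gave 1462 to 1844 genes.

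Among lists fixed before the data were examined, 14 of 28 passed in eyFLP wts- discs with the preset correlation between genes and 7 with an estimated one. Photoreceptor differentiation and ommatidial assembly was lower (median -3.41, adjusted p = 7.3e-26), with 25 of 29 members falling and none rising (28 and 0 adjusted over the list alone). The R8 ligand gene boss fell at least 13.4-fold, ru fell by 6.04 ± 0.30, the receptor gene sev by 5.86 ± 0.58 and phyl by 5.59 ± 0.24. Neuronal genes were lower (median -3.46, adjusted p = 8.86e-16). The members cpo (-5.08 ± 0.20), Appl (-4.97 ± 0.18), jeb (-4.95 ± 0.46) and futsch (-4.48 ± 0.26) led the 17 of 19 that fell (17 adjusted over the list alone). Retinal determination genes were lower too (median -1.08, adjusted p = 2.47e-05), where dac (-4.33 ± 0.40), eya (-4.28 ± 0.64), so (-3.08 ± 0.25) and eyg (-3.04 ± 0.22) fell. In this list 11 of 16 members fell and 1 rose (11 and 2 adjusted over the list alone). Antennal selectors had a median of -0.96 (adjusted p = 5.11e-08), and the antennal genes dan (-5.16 ± 0.46) and danr (-4.02 ± 0.29), with rn (-2.32 ± 0.29) and ss (-1.72 ± 0.23), were among the 10 of 16 that fell (11 adjusted over the list alone). Notch targets were lower (median -2.67, adjusted p = 8.41e-12). E(spl)m6-BFM fell at least 6.53-fold, and E(spl)mgamma-HLH (-5.14 ± 0.28), E(spl)mdelta-HLH (-4.51 ± 0.35) and E(spl)m4-BFM (-4.30 ± 0.61) also fell, within 12 of 17 members that fell and 1 that rose (13 and 1 adjusted over the list alone).

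Lists that were higher in eyFLP wts- discs were led by JNK, JAK-STAT and wound response (median 1.38, adjusted p = 3.37e-14), in which 19 of 26 members rose and 2 fell (21 and 2 adjusted over the list alone). The transcription factor gene Ets21C rose by 5.29 ± 0.77, whereas PGRP-LA fell at least 11.1-fold. Yki target genes were higher (median 0.92, adjusted p = 3.71e-08), with 12 of 21 members rising and 2 falling (13 and 3 adjusted over the list alone). Besides upd3 and Ilp8, upd2 (4.58 ± 0.34) and chinmo (4.10 ± 0.29) rose. Ribosome biogenesis passed with the preset correlation (median 0.39, adjusted p = 2.94e-05), but had an adjusted p = 0.113 with an estimated correlation. Its members dm (Myc, 0.92 ± 0.14), Non1 (0.85 ± 0.16), mbm (0.63 ± 0.17) and pit (0.58 ± 0.14) rose, 9 of 22 in all (13 adjusted over the list alone). Cell cycle and DNA replication had an adjusted p = 0.0302 with the preset correlation and an adjusted p = 0.394 with an estimated correlation. Orc2 (0.92 ± 0.22), RnrL (0.79 ± 0.15) and Mcm5 (0.73 ± 0.18) rose while the cyclin-dependent kinase inhibitor gene dap fell by 0.92 ± 0.15, among 8 of 34 that rose and 3 that fell (the same numbers adjusted over the list alone). Hippo pathway components did not pass (median -0.07, with a test direction upward, adjusted p = 0.77), although Wbp2 (0.99 ± 0.23), ft (0.77 ± 0.17) and jub (0.52 ± 0.17) rose within it, 5 of 27 rising and 2 falling (5 and 3 adjusted over the list alone).

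The optix model expresses active Yki from a transgene in part of the eye field. CG4476 rose from 0.15 ± 0.13 CPM (n = 3) to 13.9 ± 1.91 CPM (n = 2), by 6.28 ± 0.64. The long noncoding RNA CR43870 (5.93 ± 0.37), CG4462 (5.41 ± 0.79), CG1537 (5.38 ± 0.47) and the peptide receptor gene CCHa2-R (5.04 ± 0.59) followed. Swim, which encodes a secreted factor that binds Wingless, rose by 4.95 ± 0.31, from 3.07 ± 0.99 to 92.6 ± 40.6 CPM. The small nucleolar RNA snoRNA:Me18S-U1356c (4.26 ± 0.55), CG4822 (4.23 ± 0.71), CG43693 (4.18 ± 0.52) and the corneal protein gene retinin (4.14 ± 0.40) were the other rises. The cytochrome P450 gene Cyp4p2 fell by 6.63 ± 0.49, from 46.4 ± 17.6 to 0.47 ± 0.18 CPM. The body-colour gene y (from 25.6 ± 8.29 to 0.277 ± 0.222 CPM) and the X-linked noncoding RNA CR40469 (-5.93 ± 0.32) also fell. Both lie near the tip of the X chromosome, within the first 361245 bases of its dm6 sequence. Further falls were seen in ect (-5.57 ± 0.55), CG14516 (-5.50 ± 0.36), the cadherin gene Cad88C (-5.49 ± 0.38) and twit (-5.48 ± 0.31). CG15765 (-5.17 ± 0.34), the rhomboid-family gene ru (-4.93 ± 0.26) and CG34391 (-4.87 ± 0.32) ended the 10 largest falls. The adjusted p of these 20 genes was at most 0.000187. In all, 1699 of 8693 genes passed, 784 upward and 915 downward, and 950 changed at least 2-fold. A fit of the optix libraries alone called 554 genes, 174 upward and 380 downward. Without optix yki3SA replicate 2 the count was 818, and without replicate 1 it was 2199.

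Of the lists, 9 passed in the optix model and 3 kept their call with an estimated correlation. Neuronal genes were lower (median -3.13, adjusted p = 1.65e-18), with nSyb (-4.27 ± 0.31), Nrx-1 (-4.23 ± 0.41), futsch (-3.81 ± 0.24) and brp (-3.75 ± 0.38) among 15 of 19 that fell (16 adjusted over the list alone). Photoreceptor differentiation was lower (median -1.99, adjusted p = 2.03e-22). The zinc-finger genes nerfin-1 (-4.75 ± 0.43) and scrt (-4.37 ± 0.19), with boss (-4.15 ± 0.86), were among the 25 of 29 that fell, while 3 rose (25 and 3 adjusted over the list alone). Yki target genes were higher (median 0.28, adjusted p = 0.00792). The members upd3 (2.45 ± 0.78), chinmo (1.98 ± 0.27), the upstream Hippo gene kibra (1.74 ± 0.12) and dm (1.09 ± 0.14) led 7 of 21 that rose, and 1 fell (7 and 1 adjusted over the list alone). JNK, JAK-STAT and wound response had an adjusted p = 0.0129 with the preset correlation and an adjusted p = 0.134 with an estimated correlation. In it Atf3 rose by 1.74 ± 0.29 and egr, the TNF ligand gene, fell by 1.76 ± 0.27, within 8 of 26 that rose and 3 that fell (13 and 3 adjusted over the list alone). Notch targets were lower (adjusted p = 0.0109, and adjusted p = 0.321 with an estimated correlation), where E(spl)mgamma-HLH fell by 3.83 ± 0.26 and fng rose by 1.43 ± 0.20, 3 of 17 falling and 1 rising (3 and 1 adjusted over the list alone). Retinal determination genes did not pass as a list (median -0.34, adjusted p = 0.132), yet dac (-2.73 ± 0.35), so (-2.60 ± 0.25), eya (-2.24 ± 0.60) and hh (-1.01 ± 0.14) fell, among 6 of 16 that fell and 1 that rose (8 and 3 adjusted over the list alone). Antennal selectors did not pass (mean -0.32, adjusted p = 0.791), with dan (-2.90 ± 0.41) and danr (-1.81 ± 0.25) among 3 of 16 that fell and Lim1 rising by 0.61 ± 0.19 (4 and 4 adjusted over the list alone). Hippo pathway components did not pass (median 0.05, with a test direction downward, adjusted p = 0.928), although mats (-0.53 ± 0.12) and hppy (-0.41 ± 0.14) fell and Tgi rose by 0.48 ± 0.16.

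In the MARCM model, yki3SA clones were compared with control clones, with the run as a term. CG8303 rose from 1.01 ± 0.23 CPM in 5 control libraries to 40.1 ± 7.78 CPM in 5 yki3SA libraries of run 1, by 5.78 ± 0.34 over both runs. The elongase-family gene CG5278 (sit, 5.76 ± 0.72), CG14608 (thw, 5.70 ± 0.27), the fatty acid synthase gene CG17374 (FASN3, 5.58 ± 0.57) and CG11529 (5.47 ± 0.60) came next. The cuticle protein gene Cpr12A (5.23 ± 0.30), CG32444 (5.21 ± 0.46), upd3 (4.91 ± 0.42), the elongase gene bond (4.84 ± 0.51) and CG32512 (4.82 ± 0.28) also rose. CG32512 was the most abundant of these, at 799 ± 86.9 CPM in yki3SA against 23.5 ± 4.87 CPM in ctrl in run 1. The serpin gene Spn100A (-5.36 ± 0.59), CG17109 (-4.99 ± 0.61) and the ecdysone-inducible gene ImpE2 (-4.53 ± 0.68) fell most, ImpE2 from 2387 ± 989 to 121 ± 56.8 CPM in run 1. CG9021 (-4.51 ± 1.47), Cpr97Ea (-4.38 ± 0.87), the fat body protein gene Fbp1 (-4.29 ± 1.05) and Spn43Aa (-4.28 ± 0.72) fell as well. CG9150 (-4.26 ± 0.40), CG15905 (-4.24 ± 0.51) and CG1273 (-3.95 ± 0.43) completed the 10 largest falls. The adjusted p was at most 0.02 for CG9021 and at most 0.00244 for the other 19. With the replicate number as a block CG9021 had an adjusted p of 0.0764 (-3.95). Of 8927 genes, 3070 passed, 1542 upward and 1528 downward, and 1605 changed at least 2-fold, 479 upward and 1126 downward. Upper-quartile scaling moved the median of all genes by -0.11 and the rising share of calls from 50.2% to 38.2%. Run 1 alone gave 2266 genes. Of the 2883 called genes with a value in both runs, 2819 had the same sign in each, which calling on both runs together favours. Across 8020 genes, which are not independent replicates, Pearson's r between the runs was 0.789.

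Differentiation lists fell in MARCM yki3SA discs as well, with 17 of 28 lists called and 10 kept with an estimated correlation. Photoreceptor differentiation was lower (median -2.46, adjusted p = 2.76e-20), and 25 of 29 members fell with none rising (25 adjusted over the list alone). The zinc-finger gene sens fell by 3.48 ± 0.28, ru by 3.48 ± 0.31, sev by 3.41 ± 0.35 and nerfin-1 by 3.21 ± 0.30. Neuronal genes were lower with the preset correlation (median -2.49, adjusted p = 8.67e-09), with an adjusted p = 0.0697 with an estimated correlation, and jeb (-3.42 ± 0.29) and futsch (-3.19 ± 0.19) were at the head of the 14 of 19 that fell, while 2 rose (the same adjusted over the list alone). Retinal determination genes were lower (median -1.40, adjusted p = 3.74e-06), with eyg (-2.76 ± 0.30), dac (-2.68 ± 0.28), eya (-2.21 ± 0.39) and toe (-1.97 ± 0.28) among 11 of 16 falling and 1 rising (the same adjusted over the list alone). Antennal selectors were lower (median -1.66, adjusted p = 9.07e-11), and danr (-3.08 ± 0.27) fell at the head of 13 of 16 members, dan, Lim1 and ss next to it (14 adjusted over the list alone). Of the 17 Notch targets, 16 fell and 1 rose (median -2.51, adjusted p = 3.22e-09, the same counts adjusted over the list alone), led by E(spl)m6-BFM (-5.42 ± 0.79), Him (-3.50 ± 0.79) and E(spl)mgamma-HLH (-3.37 ± 0.37). Yki target genes were higher (median 0.63, adjusted p = 6.28e-06), and upd2 (4.92 ± 0.46), os (upd1, 3.16 ± 0.21) and chinmo (3.14 ± 0.20) rose with upd3, 13 of 21 rising and 1 falling (14 and 1 adjusted over the list alone). JNK, JAK-STAT and wound response was higher (median 1.00, adjusted p = 2.6e-08), with 20 of 26 rising and 2 falling (21 and 2 adjusted over the list alone). Growth lists were higher too. RnrL (1.02 ± 0.12), the Cdc25 gene stg (0.81 ± 0.18), Orc2 (0.80 ± 0.28, and 0.77 with an adjusted p of 0.0596 with the replicate block) and dup (0.79 ± 0.20) rose in cell cycle and DNA replication (median 0.51, adjusted p = 0.000166, 16 of 34 rising and 1 falling, 19 and 1 adjusted over the list alone). In ribosome biogenesis, mbm (0.75 ± 0.17), pit (0.57 ± 0.09), NHP2 (0.57 ± 0.12) and Nop60B (0.56 ± 0.17) rose (median 0.49, adjusted p = 0.000252, 11 of 22 rising, 13 adjusted over the list alone). Hippo pathway components did not pass (median 0.02, adjusted p = 0.733), with lft falling by 1.04 ± 0.29 and Tgi rising by 0.64 ± 0.12. Among wing and other disc selectors, vg, the partner of Sd in wing formation, rose by 4.78 ± 0.17, from 2.69 to 5.24 CPM in the controls to 94.6 to 125 CPM in run 1, although the list had an adjusted p of 0.753. In that list kni rose by 2.33 ± 0.16, and Scr (-2.71 ± 0.44) and bi (-2.13 ± 0.16) fell.

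**Figure D1:**
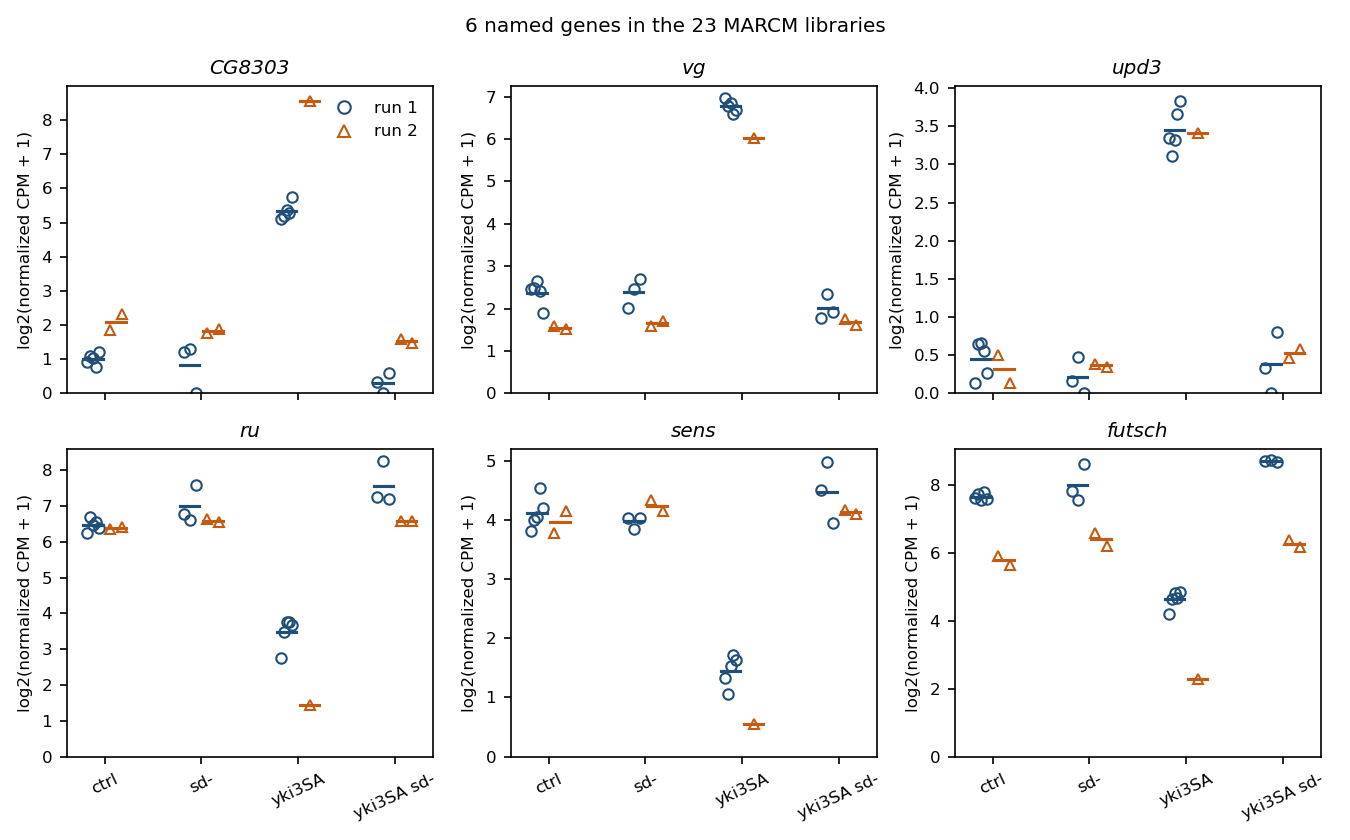
Each panel shows one gene in the 23 MARCM libraries, with the group on the horizontal axis and log2 of normalized CPM plus 1 on the vertical axis, where circles are run 1 libraries, triangles are run 2 libraries and bars are means. The 5 run 1 yki3SA libraries held 94.6 to 125 CPM of vg and 5.72 to 12.6 CPM of ru, against 2.44 to 4.07 CPM of vg and 146 to 303 CPM of ru in the 3 run 1 yki3SA sd- libraries.

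The 3 models share no library, and each answers whether Yki activation reaches the same transcripts by a different route. Among 8484 genes tested in both fits, 239 rose in all 3 models and 551 fell in all 3, where independent lists of these sizes would share 14.8 and 21.0. Fits of only the groups compared, chosen for this count after seeing the data, gave 85 and 331. Another 139 genes were called upward in one model and downward in another. The serine protease inhibitor gene Spn47C rose by 4.09 ± 0.36 in eyFLP wts-, 3.52 ± 0.39 in optix yki3SA and 4.02 ± 0.59 in MARCM yki3SA. The gene CG34301 rose at least 3.62-fold and at least 32.6-fold in eyFLP and optix discs, whose controls had no counts, and by 5.29 ± 0.83 in MARCM discs. The noncoding RNA CR45734 (3.76 ± 0.56, 4.40 ± 0.93 and 5.10 ± 0.56 in eyFLP, optix and MARCM), CG2975 (4.48 ± 0.72, 2.85 ± 0.72 and 3.98 ± 0.33) and the transglutaminase gene Tg (3.45 ± 0.52, 2.83 ± 0.68 and 3.10 ± 0.38) rose in each. So did CG7294 (3.52 ± 0.38, 2.78 ± 0.45 and 3.80 ± 0.41), CG7059 (3.58 ± 0.60, 2.77 ± 0.61 and 4.29 ± 0.73), the transcription factor gene apt (3.27 ± 0.22, 2.71 ± 0.21 and 3.02 ± 0.23), ltl (2.69 ± 0.21, 3.73 ± 0.21 and 3.33 ± 0.27) and Esyt2 (4.57 ± 0.48, 2.47 ± 0.42 and 4.71 ± 0.29). Falls common to the models, in the order of fitted changes that for genes without counts in one group exceed the bounds given, included CG14312 (at least 7.25-fold in eyFLP, then -4.45 ± 0.97 in optix and -3.98 ± 0.65 in MARCM), Osi4 (-7.08 ± 0.72, -4.48 ± 0.61 and -3.91 ± 0.32) and Cpr97Ea (-3.85 ± 0.41, -4.81 ± 0.60 and -4.38 ± 0.87). The hairy-family repressor gene Side (Sidpn; -4.88 ± 0.53, -4.31 ± 0.53 and -3.75 ± 0.40), CG31619 (nolo; -4.38 ± 0.35, -3.61 ± 0.31 and -3.74 ± 0.34), CG13203 (at least 11.9-fold in eyFLP, then -4.92 ± 0.99 and -3.59 ± 0.48) and CG9395 (at least 7.73-fold in eyFLP and 4.99-fold in optix, then -3.52 ± 0.68 in MARCM) fell in all 3. The small heat shock gene Hsp67Bc (-5.82 ± 0.34, -4.24 ± 0.31 and -3.52 ± 0.30), the eye-specific protein kinase C gene inaC (-7.06 ± 0.94, -3.67 ± 0.74 and -3.51 ± 0.45) and CG34391 (-6.32 ± 0.34, -4.87 ± 0.32 and -3.49 ± 0.38) completed the 10 genes. Shared rises had median changes of 1.42, 1.06 and 1.36 in eyFLP, optix and MARCM. For the shared falls, genes without counts in one group set at their bounds, the medians were -3.13, -2.22 and -2.34. In pairs, 333 genes rose and 600 fell in both eyFLP and optix, against 82.2 and 123 for independent lists. Fold changes across these 8484 genes, which are not independent replicates, had a Pearson's r of 0.612 between eyFLP and optix, 0.757 between eyFLP and MARCM and 0.558 between optix and MARCM.

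Loss of sd alone asks what Sd does in discs without extra Yki. Cpr92A rose from 4.18 ± 1.10 CPM (n = 5) to 18.3 ± 8.21 CPM (n = 3) in run 1, by 1.93 ± 0.34, and the receptor gene mthl3 rose by 1.34 ± 0.26, while its relative mthl8 fell by 3.61 ± 0.56. The fitted mthl3 change was 1.96 in run 1 and 0.11 in run 2. Chosen after their values were seen, the remaining calls were rises of the ciliary gene Tektin-C (5.75 ± 0.65), CG2187 (5.53 ± 0.89), CG32364 (tut, 3.21 ± 0.44), CG32055 (2.69 ± 0.48) and the body-colour gene y (0.395 CPM in ctrl and 5.31 ± 8.10 CPM in sd- in run 1, with the highest value of 14.7 CPM in replicate 3 and the lowest of 0.589 CPM, and 0.1 and 15.5 CPM in run 2), and a fall of Cyp6a23 (-2.71 ± 0.51). The noncoding RNA CR40469, near the tip of the X chromosome like y, was at 20931 to 27038 CPM in sd- and 307 to 433 CPM in ctrl in run 1. In run 2 it was at 13.5 to 14.4 CPM and 25.7 to 28.3 CPM. The sd gene itself lies on the X chromosome, so sd- discs carry a mutant X chromosome that ctrl discs lack. Whether these chromosomes also differ near the tip was not tested. The changes of y and CR40469 therefore cannot be told apart from such a difference. Without sd- replicate 3 y had an adjusted p of 0.0572. Of the other calls mthl3, Cyp6a23, CG32055 and Cpr92A lost the call without at least 1 library. Tektin-C, CG32364 and mthl8 passed in each of 12 such fits. CG2187 passed in 6 of them and was not tested in the rest. These 9 of 8927 genes passed in edgeR, against 305 at an unadjusted p under 0.05 and 22 in DESeq2. Run 1 alone called 18 and run 2 alone 423, and Pearson's r between the runs across 8020 genes was 0.0725. All 7 called genes with a value in both runs had the same sign in each, but calling on both runs together favours such genes. None of the 21 Yki target genes passed, with E2f (E2f1) at -0.16 ± 0.14, dally at 0.01 ± 0.12, ft at 0.29 ± 0.26 and th (Diap1) at -0.05 ± 0.16. No list kept a call with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 0. With the preset correlation 10 lists passed. Photoreceptor differentiation had a median of 0.13 (adjusted p = 0.000271, and adjusted p = 0.409 with an estimated correlation), while fat body and serum proteins had a median of -1.37 (adjusted p = 1.98e-08, and adjusted p = 0.0699 with an estimated correlation).

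Expression of yki3SA in sd mutant clones was compared with sd mutant clones, to see what remained of the yki3SA response without Sd. Genes at the head of the response in sd+ clones had no called rise here. In run 1 the yki3SA sd- libraries held 2.44 to 4.07 CPM of vg against 3.06 to 5.48 CPM in sd-, 0 to 0.751 CPM of upd3 against 0 to 0.391 CPM. CG8303 was lower than in sd- without passing (-0.90 ± 0.45, adjusted p = 0.223), at 1.79 to 1.99 CPM against 2.44 to 2.69 CPM in run 2 and 0 to 0.5 against 0 to 1.46 CPM in run 1. The genes that passed were few. The RNA snoRNA:Me18S-U1356c rose by 4.47 ± 0.53, from 0.624 to 16.9 CPM in run 1 and, at a far lower level, from 0.0169 CPM (1 count) to 0.156 CPM (9 counts) in run 2. The noncoding RNA CR45668 rose by 1.64 ± 0.26. Lasp, an actin-binding protein gene, fell by 1.11 ± 0.22. Chosen after their values were seen, the others were CG12607, which rose at least 61.4-fold from no counts, CG18853, which fell at least 40.6-fold to none, and Tektin-C (-4.46 ± 0.67), CG6912 (-4.04 ± 0.69), CG44815 (-3.43 ± 0.68), CG32055 (-3.05 ± 0.49), CG17470 (-2.67 ± 0.47), CG9510 (-2.02 ± 0.35) and CG31477 (-1.55 ± 0.30), which fell. These were 12 of 8927 genes, while 2115 had an unadjusted p under 0.05 and DESeq2 called 161. Of these, 6 passed whichever library was left out (snoRNA:Me18S-U1356c, CR45668, CG12607, CG18853, Tektin-C and CG6912), and Lasp passed in 2 of 10 such fits. Tektin-C and CG32055, which fell here, had called rises in sd- against ctrl, and both comparisons use the sd- libraries. In runs 1 and 2 Tektin-C was at 0.0429 and 0.864 CPM in yki3SA sd-, nearer ctrl (0.176 and 0.201 CPM) than sd- (9.06 and 8.79 CPM). Removing one library gave 6 genes (without sd- run 2 replicate 1) to 31 (without yki3SA sd- replicate 3). Run 1 alone called 1429 genes and run 2 alone 331, and Pearson's r between the runs across 8020 genes was 0.0125.

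The gene lists that moved with yki3SA in sd+ clones had small changes here. Photoreceptor differentiation had a mean of -0.03 (adjusted p = 0.874, 0 of 29 passing, 0 adjusted over the list alone), with aos at 0.87 ± 0.34 (adjusted p = 0.18), scrt at 0.19 ± 0.22, elav at 0.11 ± 0.12 and sca at 0.33 ± 0.20. Yki target genes had a median of -0.05 (adjusted p = 0.972), with ft at 0.64 ± 0.28, th at -0.35 ± 0.18, dally at -0.11 ± 0.13 and E2f at -0.08 ± 0.15, and 0 of 21 passed (0 adjusted over the list alone). JNK, JAK-STAT and wound response had an adjusted p of 0.347, cell cycle and DNA replication one of 0.178 and ribosome biogenesis one of 0.972. Neuronal genes were higher with the preset correlation (median 0.31, adjusted p = 0.00814) but had an adjusted p = 0.595 with an estimated correlation, and hemocyte genes (median 0.52, adjusted p = 0.00234) likewise had an adjusted p = 0.595 with an estimated correlation. Of the hemocyte genes 8 of 18 rose when adjusted over the list alone and 0 over all genes. Cytosolic ribosomal proteins, at -0.26 in the median (adjusted p = 1.45e-07), had that adjusted p = 0.595 with an estimated correlation too. Their median was -0.38 in run 1 alone, -0.11 in run 2 alone (76 of 78 genes lower) and -0.17 without 3 run 1 libraries chosen after seeing the data (sd- replicate 3 and yki3SA sd- replicates 1 and 2). The 333 genes raised in both eyFLP and optix discs had a median change of 0.88 in MARCM yki3SA against ctrl. In yki3SA sd- against sd- their median was -0.07, at percentile 6.52 of 10000 random sets of the same size and expression. The 600 genes lowered in both had a median of -2.20 in yki3SA against ctrl, below all random sets, and 0.10 in yki3SA sd- against sd-, above all of them. The libraries compared to choose both sets are not compared in these contrasts, but the MARCM ctrl and yki3SA libraries of run 1 were in the fit that called them. Sets called in fits of the eyFLP or the optix libraries alone, an alternative chosen after seeing the data, held 106 and 341 genes, with medians of 1.58 and -2.49 in yki3SA against ctrl. In yki3SA sd- against sd- these medians were 0.13 (percentile 99.89) and 0.13, so the sign of the raised set's small median depends on how it was chosen. In sd- against ctrl, whose sd- libraries are also the reference of yki3SA sd- against sd-, the median of the raised genes was -0.09, below all random sets, and that of the lowered genes 0.12, above all of them.

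**Figure D2:**
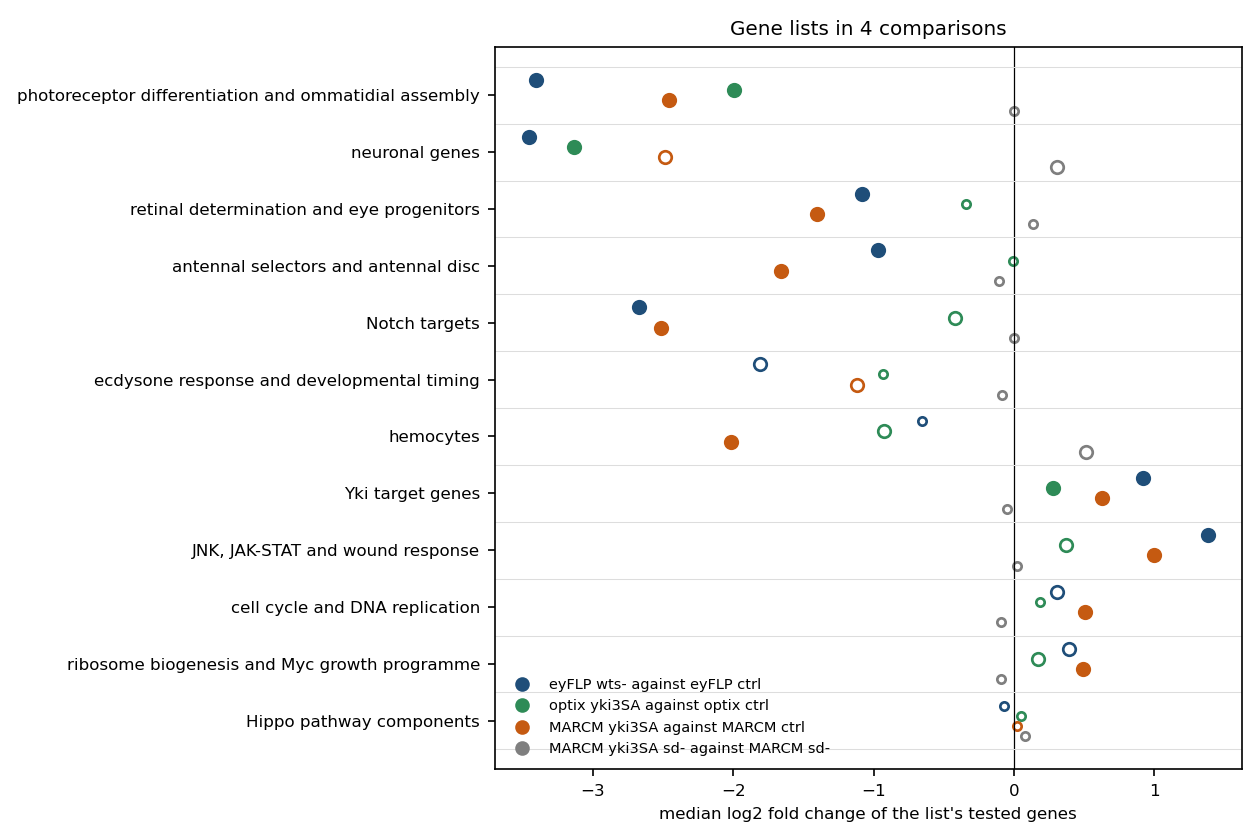
Median log2 fold change (horizontal axis) of the tested members of 12 gene lists in 4 comparisons, by colour, where filled points passed with the preset and the estimated correlation, large open points passed with the preset correlation only and small open points passed with neither. Photoreceptor differentiation stood at -3.41, -1.99 and -2.46 in eyFLP, optix and MARCM yki3SA and at 0.003 in yki3SA sd- against sd-.

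**Figure D3:**
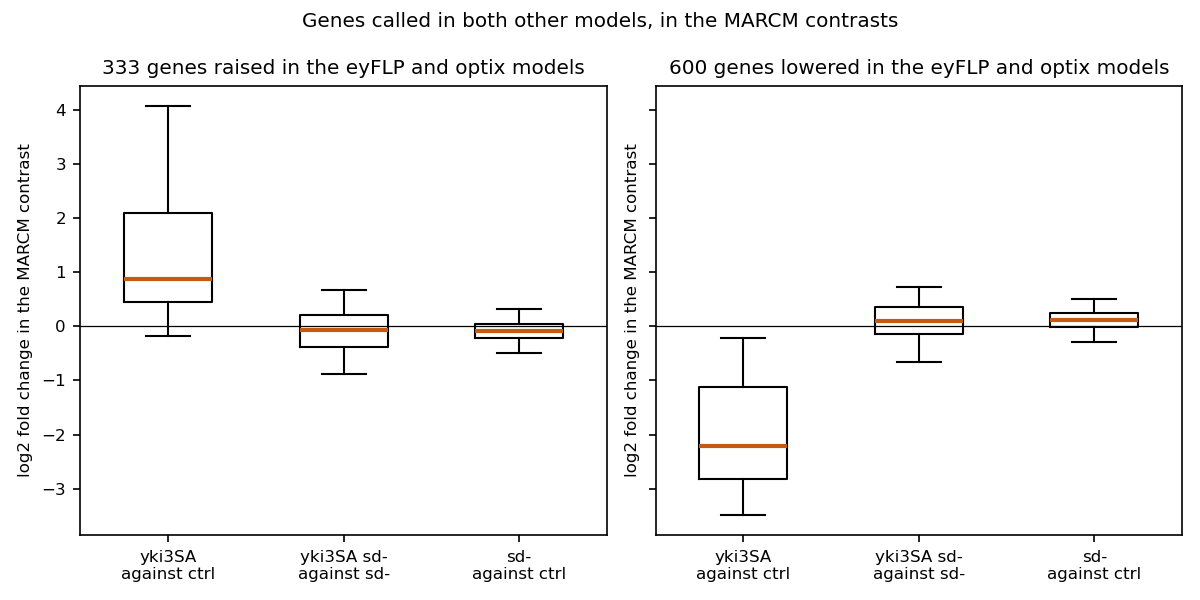
Log2 fold changes (vertical axis) in 3 MARCM contrasts of the 333 genes raised and the 600 genes lowered in both the eyFLP and optix models, with boxes at the quartiles, a line at the median and whiskers at the 5th and 95th percentiles. Medians were 0.88, -0.07 and -0.09 for the raised genes and -2.20, 0.10 and 0.12 for the lowered genes.

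Removing sd from yki3SA clones was also examined directly, as yki3SA sd- against yki3SA. In run 2 these groups differ in chromosome arm and Gal4 driver too. In run 1 yki stood at 2.87 to 10.4 CPM in yki3SA sd- against 47.7 to 85.5 CPM in yki3SA. Neither difference can be told apart from the loss of sd. Genes raised by yki3SA were at the head of the falls. CG8303 fell by 6.97 ± 0.44, from 40.1 ± 7.78 CPM (n = 5) to 0.25 ± 0.25 CPM (n = 3) in run 1. Cpr12A (-6.77 ± 0.39), CG14608 (-6.18 ± 0.33), CG11529 (-5.73 ± 0.75), CG32444 (-5.70 ± 0.57) and CG7059 (-5.44 ± 0.92) fell, as did CG7294 (-5.28 ± 0.52), vg (-4.98 ± 0.20), the cuticle gene Lcp9 (-4.87 ± 0.51) and Tg (-4.83 ± 0.49). Rises were led by Spn100A (5.47 ± 0.61), CG17109 (5.38 ± 0.63) and the ankyrin gene Ank2 (4.59 ± 0.32), which went from 13.6 ± 2.91 to 325 ± 83.6 CPM in run 1. The nuclear receptor gene Hr46 (Hr3, 4.55 ± 0.60), lectin-28C (4.46 ± 0.45), ru (4.32 ± 0.33), aay (4.28 ± 0.32), CG43347 (4.27 ± 0.35), CG43861 (4.26 ± 0.41) and CG31619 (4.18 ± 0.36) rose next. All 20 had an adjusted p of 4.75e-05 or lower. The test called 4731 of 8927 genes, 2226 rising and 2505 falling, and 2412 changed at least 2-fold, 1381 rising and 1031 falling. The rising share was 47.1%, and 53.8% with DESeq2-type and 55.4% with upper-quartile scaling, so the more frequent direction depends on the scaling. Run 1 alone gave 4500. Of 4458 called genes with a value in both runs 4199 had the same sign in each, which calling on both runs together favours. Across 8020 genes Pearson's r between the runs was 0.604. Of the photoreceptor genes 28 of 29 rose (28 adjusted over the list alone, median 2.56, adjusted p = 1.64e-18), with sens at 3.79 ± 0.29, nerfin-1 at 3.45 ± 0.32 and sev at 3.40 ± 0.37. Notch targets (median 2.18, adjusted p = 3.63e-07) and retinal determination genes (median 1.63, adjusted p = 8.37e-06) were higher, the latter with dac (3.40 ± 0.29), eyg (3.20 ± 0.32), toe (2.70 ± 0.29) and ey (1.89 ± 0.19) rising. Yki target genes were lower (median -0.71, adjusted p = 0.000253), and upd2 (-4.90 ± 0.55), upd3 (-4.55 ± 0.48), os (-3.80 ± 0.25) and Ilp8 (-3.07 ± 0.47) fell with 14 of 21 members while 2 rose (the same adjusted over the list alone). Cell cycle and DNA replication was lower (median -0.47, adjusted p = 0.000212), with dpa (-1.45 ± 0.33), RnrL (-1.36 ± 0.13), Rbf (-1.19 ± 0.29) and Mcm5 (-1.19 ± 0.17) falling.

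The interaction term asks whether the yki3SA effect differed between sd mutant and sd+ clones. In run 2 it also takes in the chromosome arm and Gal4 driver, which differ between the sd+ and sd mutant groups. In run 1 the term also takes in other differences of the yki3SA sd- libraries. There yki was at 2.87 to 10.4 CPM against 47.7 to 85.5 CPM in yki3SA, and RpL41 at 1009 to 8889 CPM against 11145 to 14432 CPM. These cannot be told apart from the loss of sd. The interaction was most negative for genes that yki3SA raised. CG8303 had an interaction of -6.67 ± 0.56, CG14608 one of -5.94 ± 0.42, Cpr12A one of -5.93 ± 0.47, CG11529 one of -5.69 ± 1.15 and Tg one of -5.32 ± 0.62. Next came vg (-5.03 ± 0.26), CG32364 (-5.00 ± 0.59), Lcp9 (-4.95 ± 0.63), CG32444 (-4.89 ± 0.83) and CG17374 (-4.81 ± 0.82). Positive interactions, in which the fitted yki3SA change was more positive without sd, included CG17109 (7.09 ± 0.87), Spn100A (5.17 ± 0.76), Cpr97Ea (4.71 ± 1.21), lectin-28C (4.46 ± 0.59) and CG1092 (4.38 ± 0.64). Glt (4.31 ± 0.51), E(spl)m5-HLH (4.19 ± 0.68) and Gs1 (4.19 ± 0.49) were also positive. The crystal cell genes PPO1 (4.84 ± 1.35) and PPO2 (4.69 ± 1.51) were positive over both runs and in run 1, but stood at -1.72 and -2.25 in run 2 alone. The adjusted p was at most 0.0239 for these 20 genes. Of 8927 genes, 2494 passed, 1337 positive and 1157 negative. Upper-quartile scaling moved the positive share from 53.6% to 65.8%. Among the 2371 called genes with a value in both runs, 2329 had the same sign in each. Of the 333 genes raised in both eyFLP and optix discs 215 had a called negative interaction and 7 a positive one, and of the 600 lowered in both 507 had a positive one and 4 a negative one.

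By list, 17 of 28 had a called interaction and 11 kept it with an estimated correlation. Photoreceptor differentiation had a positive interaction (median 2.31, adjusted p = 8.37e-21), with ru (3.84 ± 0.43), sens (3.74 ± 0.38), pros (3.43 ± 0.46) and sev (3.05 ± 0.47) among 26 of 29 members called (27 adjusted over the list alone). Neuronal genes (median 2.67, adjusted p = 2.06e-10, and a median of 2.73 with the level of the ring gland genes spok and phm as a covariate, chosen after seeing the data) included jeb (3.66 ± 0.40), futsch (3.51 ± 0.26), Nrt (3.31 ± 0.43) and nSyb (3.25 ± 0.38). Retinal determination (median 1.56, adjusted p = 2.06e-06) and antennal selector genes (median 1.69, adjusted p = 1.58e-09) were positive too, with eyg (3.16 ± 0.42), dac (3.11 ± 0.39), toe (2.85 ± 0.40) and toy (1.79 ± 0.18) in the first and danr (2.92 ± 0.38), dan (2.69 ± 0.46), ct (2.65 ± 0.23) in the second. Yki target genes had a negative interaction (median -0.59, adjusted p = 2.14e-05), led by upd2 (-5.58 ± 0.73), upd3 (-4.19 ± 0.70), Ilp8 (-3.77 ± 0.64) and os (-3.55 ± 0.33). JNK, JAK-STAT and wound response (mean -1.32, adjusted p = 1.34e-05) was negative in 16 of 26 members and positive in 2 (the same adjusted over the list alone). Cell cycle and DNA replication (median -0.53, adjusted p = 9.42e-05) and ribosome biogenesis (median -0.48, adjusted p = 0.00288) were negative, with RnrL (-1.34 ± 0.18) and stg (-1.05 ± 0.27) in the first and NHP2 (-0.81 ± 0.18) and Tif-IA (-1.12 ± 0.38) in the second. The manipulated genes themselves had interactions of -3.34 ± 1.03 for yki (adjusted p = 0.0197), -0.86 ± 0.15 for sd (adjusted p = 0.000122) and -0.73 ± 0.21 for wts (adjusted p = 0.0112).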

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

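The interaction count and the single-library values below were found by rules fixed before the data were examined. The tests of power, of outlying libraries, of the transgene, of an effect that does not need sd, of the X chromosome and of the share of males, the splits that part pairs and the comparison of measures by run were chosen after the result was seen.

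The yki3SA effect differed between sd mutant and sd+ clones for 2494 genes by the interaction term. Across 60 splits of the libraries within runs, 1 split, the real one, reached this count, and the highest other gave 1. These splits moved libraries among all 4 MARCM groups, so they test for any difference between groups. They cannot exclude chance as the source of the interaction count itself. With splits between only the groups compared, chance is argued against for MARCM yki3SA against ctrl (3070 genes real, 1 split, highest other 730). There the run 1 numbers go with a structure that the libraries share. Of the 96 splits that part all 5 same-numbered pairs the real one alone reached its count. The highest other, which kept the real run 1 groups, called 2285, and the highest with 1 pair swapped called 516 (0 with the replicate block). Chance is also argued against for sd- against ctrl (9 genes real, 1 split, highest other 1) and for yki3SA sd- against yki3SA (4731 genes real, 1 split, highest other 1030). A share of 1 in 60 is the smallest that such splits can give, without adjustment over comparisons. In sd- against ctrl the replicate block left 2 genes and a mean of at least 10 CPM left 1. For yki3SA sd- against sd- chance was not excluded, since 4 of 60 splits called as many as the real 12 genes and the highest other called 1250. A split that calls so many more genes points to a structure of the samples other than these groups.

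In 6 of 28 tests of a group on a measure the highest or lowest library lay apart, where chance alone gives about 1 in 20. Only the MARCM groups were tested. Each of them holds libraries of both runs, so differences between runs enter these tests and the excess over chance does not count single libraries. In MARCM sd- run 1 replicate 3, roX1, a noncoding RNA made in males, was at 259 CPM against 2.06 to 5.07 CPM in the other sd- libraries, and yki was at 1.45 CPM against 63.5 to 71.7 CPM. Low yki was not particular to this library, at 2.87 to 10.4 CPM in run 1 yki3SA sd- and 0 to 17.4 CPM in optix ctrl. In run 1 it was thus present in every yki3SA sd- library and absent from the other sd- libraries, so it runs partly with that comparison. In MARCM ctrl run 2 replicate 2, roX1 was at 32.4 CPM against 5.97 to 12.9 CPM. The single run 2 library of MARCM yki3SA had yki at 2146 CPM against 47.7 to 85.5 CPM in run 1, sd at 498 CPM against 673 to 740 CPM, and 6.84% of its counts in its top 10 genes against 13.0% to 14.5%. The last 2 measures differ by run: the other 6 run 2 libraries had sd at 205 to 236 CPM and 5.58% to 6.25% in their top 10 genes, and the 11 run 1 libraries of the other groups had 278 to 480 CPM and 10.9% to 15.3%.

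Few genes were called between yki3SA sd- and sd-, where yki3SA called 3070 in sd+ clones. Low power of this comparison argues poorly for the missing calls among the 600 genes lowered in the eyFLP and optix models. Their median was 0.10 here against -2.20 in sd+ clones. Without the 3 doubted run 1 libraries that median was 0.11, so they are not its source. A median does not decide whether outlying libraries lowered the number of calls. The run 1 yki3SA sd- library that was kept, replicate 3, had RpL41 at 8889 CPM. Run 1 ctrl and yki3SA libraries held 11145 to 14926 CPM of it. Nor does the median decide whether low power left other changes uncalled. Between yki3SA sd- and sd-, 2115 of 8927 genes had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. DESeq2 called 161 genes and run 1 alone 1429. Less transgene expression or smaller clones could still contribute. In run 2 the yki counts added in yki3SA sd- discs were 1.95% of those added in yki3SA discs (40.5 against 2081 CPM). The drivers differ between these groups in run 2, so expression and driver cannot be told apart there. In run 1 no added counts were seen, with yki at 2.87 to 10.4 CPM in yki3SA sd- and 1.45 to 71.7 CPM in sd-. It was at 47.7 to 85.5 CPM in yki3SA and 19.9 to 60.6 CPM in ctrl. Whether the transgene carries the yki 3' end is not given, so run 1 does not settle its level. A need for Sd in the response remains a hypothesis with these reservations.

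In run 1 alone, 1429 genes were called between yki3SA sd- and sd-. An effect of yki3SA that does not need sd would recur in run 2, yet 755 of 1397 genes (54.0%) had the same sign there. A difference between libraries that other groups also show may be a source: across these genes, which are not independent replicates, the run 1 change had a Pearson's r of 0.673 with optix ctrl minus MARCM ctrl, groups that share no library with it, and 0.529 across all genes tested. What sets those libraries apart was not tested.

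In optix yki3SA discs y, CR40469 and roX1 were lower than in the controls (roX1 by -1.19, adjusted p = 0.0651). Another X chromosome as the source of the called genes at large is argued against, because X-linked genes were called 0.988 times as often as genes of other arms. For y and CR40469 themselves a different X chromosome remains open, although the labels name the same X-linked markers for both groups; it is not tested here. Another share of male larvae is a candidate explanation for the roX genes, since roX2 fell by 1.33 (adjusted p = 0.04) and its log2 change minus that of roX1 was -0.15.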

How the results depend on the processing

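Fits of run 2 alone, without 3 doubted libraries (sd- replicate 3, yki3SA sd- replicates 1 and 2, run 1), with sample quality weights and with the level of spok and phm as a covariate, and sets and shared genes from fits of only the groups compared, were chosen after seeing the data. These libraries were doubted for their abundant transcripts: RpL41 was at 7661 CPM in that sd- library against 14024 and 14637 CPM in the other run 1 ones, and at 3869 and 1009 CPM in those yki3SA sd- libraries against 8889 CPM. Leaving them out is therefore no independent test of ribosomal protein genes. Of 20348 recomputed values of 857 named-gene results, 19471 kept their side of the threshold, and with it their direction where the gene was called. Another 783 lost the call, 83 gained one and 11 changed sign with a call in either fit. For genes called in neither fit the sign was not compared. Of 317 recomputed list tests, 240 kept their call and 77 lost it. Where a cause is not given, the cause was not tested.

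Asking also for a log2 fold change of at least 1 left 1269 genes in eyFLP, 950 in optix, 1605 in MARCM yki3SA against ctrl, 2412 in yki3SA sd- against yki3SA, 1624 in the interaction and 525 shared by the 3 models. A mean of at least 10 CPM, with fewer genes tested, left 1391, 1132, 1876, 1 (sd- against ctrl), 1 (yki3SA sd- against sd-), 1545 (interaction) and 492 shared. Fitting only the libraries of the groups compared gave 554 genes in optix and 0 between yki3SA sd- and sd-, but more in eyFLP (2824) and in yki3SA against ctrl (4025), and 416 shared by the 3 models. DESeq2 called 22 genes in sd- against ctrl and 161 in yki3SA sd- against sd-. With the replicate number as a block these counts were 2 and 4; same-numbered libraries of the other pairs of MARCM groups in run 1 had an r of -0.49 to 0.39 and share only a number. In yki3SA against ctrl, where same-numbered run 1 libraries had an r of 0.173 to 0.494, the block gave 2764 genes and changed no list call. Of the named genes there 6 lost the call (CG9021, Orc2, Cpr51A, PPO1, Lsp1alpha and Sxl). Without one library at a time, optix gave 818 (without yki3SA replicate 2) to 2199, and yki3SA sd- against sd- gave 6 to 31.

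Run 1 alone called 18 genes in sd- against ctrl and 1429 in yki3SA sd- against sd-, where the median of the 333 raised genes was -0.21 (0.13 in both runs for the 106 raised genes of the fits of eyFLP or optix alone). Run 2 alone called 5452 genes in yki3SA against ctrl, 423 in sd- against ctrl, 331 in yki3SA sd- against sd- and 4970 in the interaction. With no run term the counts were 1542 (yki3SA against ctrl), 3 (sd- against ctrl), 0 (yki3SA sd- against sd-), 2317 (yki3SA sd- against yki3SA) and 849 (interaction). Without the doubted libraries yki3SA sd- against sd- gave 23 genes. In run 1 without them, sd- against ctrl gave 53, yki3SA sd- against sd- 588 and yki3SA sd- against yki3SA 3062. Quality weights gave 48 in sd- against ctrl and 110 in yki3SA sd- against sd-. With an estimated correlation 40 list tests passed, where 85 passed with the preset one.

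Among named genes with a call in either fit, signs changed in run 2 alone for RpS4 (-0.41) and yki (0.72) in yki3SA sd- against sd-. In run 2 alone they also changed for PPO1 (-3.56) and PPO2 (-4.17) in yki3SA sd- against yki3SA. In the interaction they changed there for PPO1 (-1.72), PPO2 (-2.25) and Hsp70Ba (0.26). With quality weights PPO1 was at -0.50 and PPO2 at -0.088 in yki3SA sd- against yki3SA. Nmd3 was at 0.054 there in run 1 without the doubted libraries, where 1 yki3SA sd- library was left, and Hsp70Ba was at 0.38 in the interaction with no run term. Depth limits what a count of 0 can show: against the floor of 3 counts, bounds in eyFLP started at 3.62-fold.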

Other observations

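Blood cell, muscle and glial lists were tested in each model. With the preset correlation the hemocyte list passed in MARCM yki3SA and optix discs but not in eyFLP discs (adjusted p = 0.119), and the muscle list (adjusted p = 0.259 in eyFLP and 0.92 in optix) and the glia list (0.539 and 0.791) passed in MARCM yki3SA discs alone of the 3 models, which were not compared with each other. Hemocyte genes were lower in MARCM yki3SA discs (median -2.01, adjusted p = 5.28e-07), with lz (-2.76 ± 0.29), Glt (-2.67 ± 0.35), eater (-2.54 ± 0.38) and PPO1 (-2.50 ± 0.89, and -2.67 with an adjusted p of 0.0544 with the replicate number as a block) among 13 of 18 that fell (15 adjusted over the list alone). In optix discs they had an adjusted p of 0.00062 with the preset correlation and an adjusted p = 0.239 with an estimated correlation, and PPO1 (-3.13 ± 0.76), PPO2 (-2.97 ± 0.78) and lz (-2.96 ± 0.27) fell. Muscle and myoblast genes in MARCM yki3SA discs (median -1.07, adjusted p = 0.00011, and adjusted p = 0.134 with an estimated correlation) included falls of twi (-2.81 ± 0.47), zfh1 (-2.28 ± 0.12) and sls (-2.23 ± 0.16). Glial genes had an adjusted p of 0.0366, and adjusted p = 0.0641 with an estimated correlation, with Gs2 (-2.64 ± 0.28) falling and vir-1 rising by 2.00 ± 0.13. Central brain neuroblast and neuron genes were lower (median -1.42, adjusted p = 7.1e-06), led by mira (-3.17 ± 0.33), pros (-3.16 ± 0.33) and ase (-3.04 ± 0.81). Named after their values were seen, the ring gland genes spok (-2.25 ± 0.93, adjusted p = 0.066) and phm (phtm, -1.69 ± 0.76, adjusted p = 0.0899) ran the same way without passing and varied within groups, spok from 0.815 to 79.3 CPM in run 1 ctrl and from 1.04 to 10.8 CPM in run 1 yki3SA. With their level as a covariate, chosen after seeing the data, the median of the brain list was -1.53 and that of neuronal genes -2.48 (-2.49 without it), and 2912 genes were called. In yki3SA sd- against yki3SA both rose, spok by 3.40 ± 1.04 (adjusted p = 0.00957) and phm by 2.61 ± 0.84 (adjusted p = 0.0132), spok from a mean of 5.08 to 31.1 CPM in run 1 and from 7.26 to 206 CPM in run 2. There the covariate moved the median of the brain list from 1.75 to 1.33, of neuronal genes from 2.75 to 2.63 and of photoreceptor genes from 2.56 to 2.53, with 4445 genes called, and in the interaction the brain list was at 2.13 without and 2.15 with it. Ecdysone response genes were lower with the preset correlation (median -1.12, adjusted p = 0.000166, and adjusted p = 0.176 with an estimated correlation), with ImpE2 (-4.53 ± 0.68), Hr46 (-3.79 ± 0.57) and Blimp-1 (-3.76 ± 0.51) falling. EGFR, Dpp and Wg read-outs (median -0.40, adjusted p = 0.0137, and adjusted p = 0.0839 with an estimated correlation) included falls of pnt (-2.46 ± 0.18), salm (-2.44 ± 0.17) and rho (-2.44 ± 0.17).

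The remaining lists in MARCM yki3SA discs held changes of single genes. Fat body and serum proteins had an adjusted p of 0.00848, and adjusted p = 0.239 with an estimated correlation, where Obp56d (-3.02 ± 0.53) and Lsp1gamma (-2.87 ± 0.74) fell. Cytosolic ribosomal proteins had an adjusted p of 0.0366, and adjusted p = 0.681 with an estimated correlation, where RpLP1 (0.48 ± 0.13) and RpL13 (0.40 ± 0.10) rose. The trachea list did not pass (adjusted p = 0.0625), although trh (4.41 ± 0.48), serp (2.23 ± 0.15), dys (dysf, 1.57 ± 0.34) and Gasp (1.53 ± 0.13) rose. Sex-specific transcripts (adjusted p = 0.0682) included a fall of Yp2 (-2.36 ± 0.60), cuticle proteins (adjusted p = 0.0842) one of TwdlT (-2.83 ± 0.50) and peripodial genes (adjusted p = 0.121) one of pnr (-2.28 ± 0.33). Innate immunity (adjusted p = 0.138) held a rise of IM1 (4.07 ± 0.55), apoptosis (adjusted p = 0.515) a fall of egr (-1.53 ± 0.22) and a rise of Xrp1 (0.69 ± 0.12), and adhesion and matrix genes (adjusted p = 0.583) a rise of Timp (3.56 ± 0.35) and a fall of Mmp2 (-2.67 ± 0.28). In heat shock and oxidative stress (adjusted p = 0.99), Hsp70Bb (4.02 ± 0.43) and GstE6 (3.51 ± 0.28) rose and Hsp67Bc (-3.52 ± 0.30) and Hsp23 (-3.18 ± 0.37) fell. None of 9 salivary gland genes passed in edgeR (adjusted p = 0.753 for the list), with CrebA at -0.19 ± 0.20.

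Some single transcripts, chosen after their values were seen, had unusual distributions over the groups. The RNA snoRNA:Me18S-U1356c was at 6.59 CPM in MARCM yki3SA, 16.9 CPM in yki3SA sd- and 16.3 CPM in optix yki3SA, against 0.474 CPM in MARCM ctrl, 0.624 CPM in sd- and 0.786 CPM in optix ctrl, all in run 1. In run 2 its highest group mean was 0.156 CPM. Tektin-C was at 9.06 and 8.79 CPM in sd- in runs 1 and 2, against 0.176 and 0.201 CPM in ctrl and 0.0429 and 0.864 CPM in yki3SA sd-. CG12607 was at 16.6 CPM in eyFLP wts- and 1.21 CPM in optix yki3SA, against 0.0789 CPM in optix ctrl. In runs 1 and 2 of the MARCM model it was at 0 and 0.764 CPM in ctrl and at 0.310 and 0.340 CPM in yki3SA. It was at 1.81 and 2.78 CPM in yki3SA sd- and at 0 in sd- in both runs. The noncoding RNA CR34335 had a mean of 88788 CPM in run 1 MARCM ctrl and 3.11 CPM in run 2, against 51941 and 23.2 CPM in sd-. CR40469 went the other way in each run, at 23775 CPM in sd- against 349 CPM in ctrl in run 1 and at 14.0 against 27.0 CPM in run 2. The cause was not tested.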
